A study of Marchantia polymorpha and Arabidopsis thaliana with 54 samples.

How the data were processed

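RNA was extracted as total RNA from whole seedlings with RNeasy columns and sequenced on a NovaSeq instrument, per the labels' protocols. The authors deposited read counts per gene for 27655 genes in 18 libraries of Arabidopsis thaliana as a single table of raw counts. The submitters' processing notes name fastp 0.24.0, STAR 2.7.9a, featureCounts and Subread 2.0.6, without their settings. The genome build, the annotation, the strand setting of the counting and the treatment of reads that map to several places were not given in the sources used here. Between 75.4% and 83.3% of the non-zero counts of a library were even numbers, so the mates of a pair appear to have been counted singly for most fragments, and an alternative with halved counts was added after the data were seen. All 54 samples of the series were read, and 36 samples of Marchantia polymorpha, for which no table was used here, were not analysed here. The series is about chromatin in heat, and chromatin data were not used here.

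Samples were grouped by genotype and treatment as their labels give them, with batch 1 or batch 2 as a further label. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Within each group the replicate pairs were compared by chi-square on halved counts, and all 36 pairs differed beyond sampling noise, so no library was counted as a repeat of another. Totals lay between 58370609 and 110875442 counts per library, so counting error is small for all but the rarest transcripts. Intervals and floors given for counts cover counting error only.

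Tests used edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, robust glmQLFit and glmQLFTest), and 22696 genes passed the filter. A single quasi-likelihood model with a term per group and a term for batch was fitted to all 18 libraries, with a common dispersion of 0.0244. The batch term is shared, so the model takes the batches to differ alike in both lines. A test of genotype by batch in the controls called 1332 genes, for which this does not hold. Heat and interaction estimates of such genes may be off. The 5 comparisons were heat in Col-0, heat in the line labelled eTK, the difference of these responses as an interaction, and the lines against each other in control and in heat. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 with no fold threshold. Fold changes are log2 with their SE, and levels are CPM with TMM factors. The SE was not estimated directly. It was taken as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Where a group has almost no counts, such an SE may be far too small. The mean TMM factor was 1.11 in Col-0 control, 0.655 in Col-0 heat, 1.11 in control libraries labelled eTK and 1.02 in their heat libraries. A count of genes that rose less in the line labelled eTK takes those called higher in heat in Col-0 and lower in the interaction. The control comparison was repeated within each batch. Where a group had no count, a fold is given against a floor of 3 counts over the group. Such folds may be too high as lower bounds, and counting intervals too narrow, since mates appear to have been counted singly.

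There were 22 gene lists: heat shock factors, small heat shock proteins, HSP70, HSP90 and HSP100 chaperones, co-chaperones, heat-responsive regulators, heat stress memory, the unfolded protein response of the endoplasmic reticulum, oxidative stress enzymes, galactinol synthases, abscisic acid response, light harvesting and Rubisco, cell cycle, splicing factors, chromatin regulators, ONSEN retrotransposons, clock and thermomorphogenesis, early general stress and touch, defence, root tissue markers, stomatal lineage markers, seed and embryo markers, and reference genes. ONSEN members had no entry in the table and were not analysed here. Some genes stand in more than 1 list, as HSFA2 does. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of a comparison. Camera compares a list with all other genes, and fry, an alternative, asks whether its genes move one way on balance. Named genes were chosen by a rule: 16 core genes in each comparison, the 5 largest rises and falls per comparison among called genes whose libraries did not overlap and whose higher group reached 5 CPM, and the 2 called members of each list with the largest change (4 for the lists of heat shock factors, small heat shock proteins, HSP70, HSP90 and HSP100 chaperones, and heat-responsive regulators). Groups, comparisons, lists, this rule and the alternatives other than halved counts were fixed before the data were examined. Positions and descriptions come from TAIR10.1, to which 27445 nuclear identifiers of the table matched, and another 88 were plastid and 122 mitochondrial. Close copies, such as BIP1 and BIP2, HSC70-1, HSC70-2 and HSC70-3, HSP90.2, HSP90.3 and HSP90.4, the LHCB and RBCS genes and CBF1 to CBF3, may share reads and are uncertain as single genes, as are overlapping and antisense genes.

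The model was tested on simulated data, with counts drawn for 22696 genes from the means and library sizes of these libraries and 200 genes changed. For heat in Col-0, 45.6%, 72.9% and 94.5% of genes changed 1.5-fold, 2-fold and 4-fold were called, and 47.5%, 76.5% and 88.7% for heat in the line labelled eTK. For the interaction these shares were 10.7%, 58.3% and 93.8%, for the lines in control 56.9%, 70.0% and 91.2%, and for the lines in heat 37.9%, 63.8% and 95.9%. Between 2.7% and 6.41% of the calls were false. The simulated counts held no batch or other group effect, and few genes changed, while 25.15% to 63.66% of genes were called in the real comparisons. The adjusted p depends on how many genes change, so these shares need not hold for the real tests. Alternatives were median-of-ratios size factors, library size alone, TMM without heat shock, chaperone and organelle genes, no filter on low counts, DESeq2 1.42.0, limma-voom, batch 1 libraries alone, no batch term, the replicate number as a block, a fold threshold of 2, only the groups compared, no organelle genes, and each of the 18 libraries left out in turn. Other groupings of the libraries, at most 100 for each comparison, were tested in the same model.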

Results

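RNA-seq read counts of 27655 genes were analysed for 18 libraries of Arabidopsis thaliana seedlings. The seedlings were 7 days old, grew on agar at 22 °C in continuous light, and were either left at that temperature or moved to 37 °C for 1 h. The 4 groups were Col-0 in control (6 libraries), Col-0 in heat (3), eTK in control (6) and eTK in heat (3). Col-0 is the wild-type accession, and eTK is a line whose label names the heat shock factor genes HSFA1A, HSFA1B and HSFA1D as knocked out. Replicates 1 to 3 of each group belonged to batch 1, and replicates 4 to 6 of the control groups to batch 2, so that heat was measured in batch 1 only. The transcript of 1 of the 3 genes, HSFA1A, was higher in this line in control, as given below. Transcript levels alone cannot show whether a gene is knocked out, and the second line is therefore called by its label throughout.

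The libraries held between 58370609 and 110875442 counts each. The Col-0 control libraries held 89224416, 110875442, 63270189, 70616128, 80112940 and 67358677 counts in replicates 1 to 6, and the Col-0 heat libraries 72670045, 58370609 and 59011969. The control libraries labelled eTK held 68955151, 94037169, 104942533, 77452179, 65985426 and 74689952 counts, and the heat libraries labelled eTK 59991169, 61808199 and 64844153. Small heat shock protein, HSP70, HSP90 and HSP100 genes together took 0.445% ± 0.0413 of the counts in Col-0 control libraries (SD, n = 6) and 17.1% ± 0.816 in Col-0 heat libraries (n = 3). In libraries labelled eTK the same genes took 0.306% ± 0.0406 in control (n = 6) and 0.358% ± 0.0382 in heat (n = 3). The first 3 principal components carried 42.9%, 27.3% and 8.02% of the variance between libraries.

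**Figure D1:**
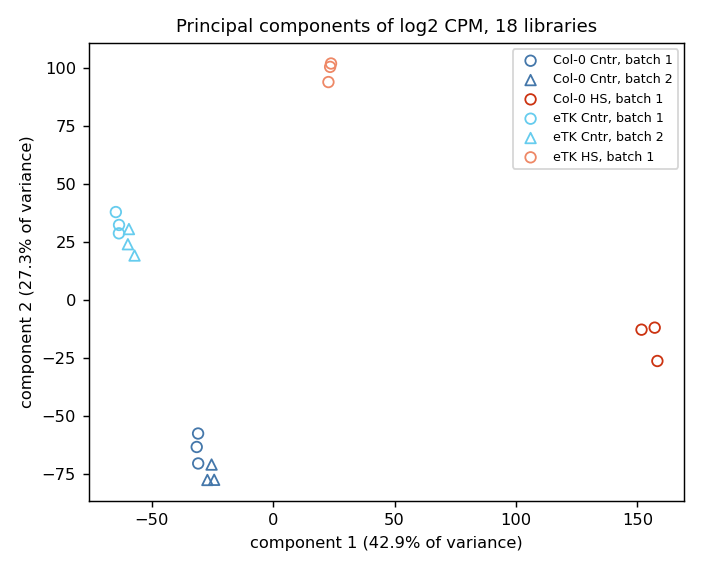
Principal components of log2 CPM over the 18 libraries, each point a library, with the percent of variance of each component on its axis (42.9% and 27.3%). Colours mark the 4 groups, and circles and triangles mark batch 1 and batch 2.

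The expression of the targeted genes was compared first, since it bears on the label of the knockout line. HSFA1A (AT4G17750, TAIR10.1 chromosome 4, 9869818 to 9871646), HSFA1B (AT5G16820, chromosome 5, 5530195 to 5532889) and HSFA1D (AT1G32330, chromosome 1, 11656964 to 11660471) encode factors that start the transcriptional heat shock response. HSFA1B was at 12.4 ± 2.04 CPM in Col-0 control libraries and 1.45 ± 0.315 in control libraries labelled eTK (mean ± SD, n = 6 each), a log2 difference of −3.09 ± 0.14 (SE, adjusted p = 4.02e-12). HSFA1D was at 14.6 ± 0.627 and 5.55 ± 0.564 CPM in the same groups (−1.40 ± 0.078, adjusted p = 1.19e-10). HSFA1A went the other way, although the label names it as knocked out: it was at 6.24 ± 0.922 CPM in Col-0 and 12.1 ± 1.62 CPM in libraries labelled eTK, and higher by 0.96 ± 0.12 on the log2 scale (adjusted p = 9.1e-06). That difference was 0.95 in batch 1 and 0.97 in batch 2. In heat HSFA1B and HSFA1D were lower in libraries labelled eTK, at −3.75 ± 0.21 and −1.91 ± 0.11 (adjusted p = 2.59e-11 and 6.53e-11, n = 3 each). HSFA1A was at 2.69 ± 0.386 CPM in Col-0 heat libraries and 2.14 ± 0.596 in those labelled eTK, a difference that did not pass the test (−0.33 ± 0.19, adjusted p = 0.166) except without eTK heat replicate 1 (−0.56, adjusted p = 0.0246). HSFA1E (AT3G02990, chromosome 3, 673428 to 676428), the fourth gene of the class, was at 5.06 ± 0.793 and 5.86 ± 1.01 CPM in control and was not called there (0.21 ± 0.13, adjusted p = 0.27). In batch 1 alone the HSFA1E difference in control was 0.43 and passed the test (adjusted p = 0.0492). Counts per gene cannot tell a transcript that is cut short or cannot be translated from an intact one. The levels of these genes therefore neither show nor exclude a knockout.

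**Figure D2:**
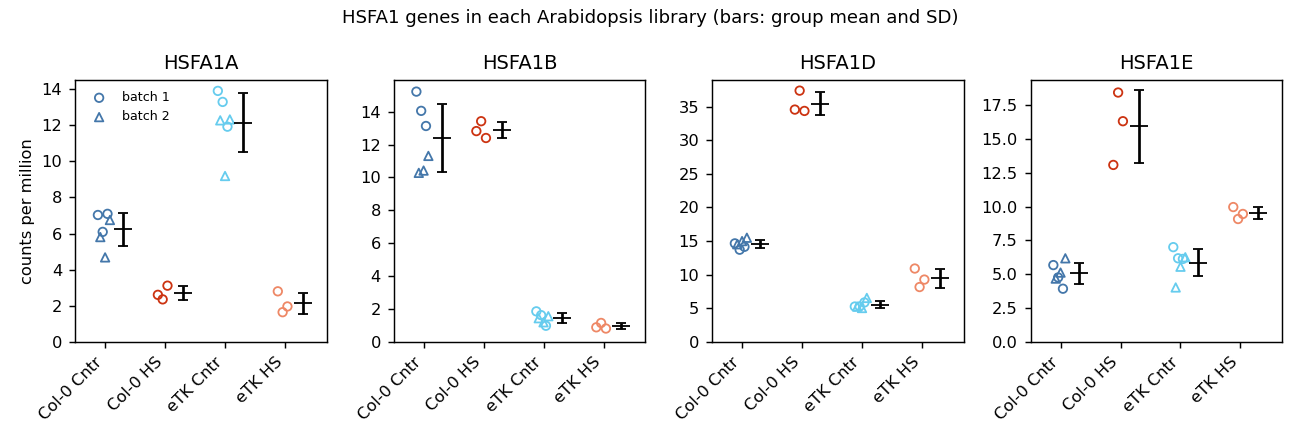
CPM of HSFA1A, HSFA1B, HSFA1D and HSFA1E in each library of the 4 groups, circles for batch 1 and triangles for batch 2, with bars for the group mean and SD. HSFA1B and HSFA1D were lower in the control libraries labelled eTK (1.45 and 5.55 CPM) than in Col-0 (12.4 and 14.6 CPM), and HSFA1A was higher (12.1 against 6.24 CPM).

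The comparison of Col-0 in heat with Col-0 in control asked which transcripts respond to 1 h at 37 °C in the wild type. Many heat shock protein transcripts rose, some from near absence, such as HSP21, and others from a clear level in control, such as HSP101. HSP21 (AT4G27670, chromosome 4, 13818825 to 13819971), a small heat shock protein of plastids, was at 0.0408 CPM in control and 2696 ± 158 CPM in heat, a rise of 16.42 ± 0.46 on the log2 scale (adjusted p = 1.16e-15). HSP101 (AT1G74310, chromosome 1, 27936508 to 27940369), a disaggregase needed for acquired thermotolerance, rose by 10.84 ± 0.17 from 15.2 ± 3.45 CPM (adjusted p = 2.8e-19). HSFA2 (AT2G26150, chromosome 2, 11135624 to 11137792), a heat shock factor that is itself made in heat, rose by 13.88 ± 0.39 from 1.04 to 9675 ± 594 CPM (adjusted p = 1.73e-15). Of 22696 genes tested, 14448 were called, 7091 higher and 7357 lower, and 2075 and 3507 of these by at least 2-fold. Under scaling by library size alone the split was 1861 higher and 15306 lower. That scaling moved the median of all genes from −0.038 to −0.75, and changes below are given relative to the trimmed-mean scaling that sets the median near 0.

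Among 19 small heat shock protein genes 17 rose and none fell, also when adjusted over the list alone (median 12.52, camera adjusted p = 5.59e-81, and adjusted p = 4.98e-10 with an estimated correlation). HSP17.6C-CI (AT1G53540), a cytosolic member, rose by 15.05 ± 0.26. All 19 HSP70, HSP90 and HSP100 genes rose, 19 when adjusted over the list alone (median 5.90, adjusted p = 5.21e-83, and adjusted p = 0.000189 with an estimated correlation). HSP70-5 (AT1G16030) rose by 11.46 ± 0.14, HSP90.1 (AT5G52640, chromosome 5, 21352557 to 21355147) by 10.60 ± 0.27 and HSP70-4 (AT3G12580, chromosome 3, 3991117 to 3993886) by 10.44 ± 0.41. All 11 co-chaperone genes rose, 11 when adjusted over the list alone (median 4.95, adjusted p = 2.9e-64, and adjusted p = 4.77e-05 with an estimated correlation), among them ROF2 (AT5G48570), an FK506-binding protein, by 10.03 ± 0.17 and HOP3 (AT4G12400) by 9.92 ± 0.18. With library size alone 9 of these 11 were higher and 1 lower. Of 15 heat-responsive regulators 12 rose and none fell, 12 when adjusted over the list alone (median 5.14, adjusted p = 9.09e-43, and adjusted p = 8.51e-06 with an estimated correlation). DREB2A (AT5G05410), a factor of drought and heat responses, rose by 8.46 ± 0.26 and the coactivator MBF1C (AT3G24500) by 8.48 ± 0.17. Of 10 heat stress memory genes 9 rose and none fell, 9 when adjusted over the list alone (median 10.21, adjusted p = 1.47e-44, and adjusted p = 3.43e-08 with an estimated correlation). APX2 (AT3G09640), a cytosolic ascorbate peroxidase of that list, rose by 12.94 ± 0.30. Of 21 heat shock factor genes 12 rose and 5 fell, 13 and 5 when adjusted over the list alone and 11 and 7 with library size alone (median 1.31, adjusted p = 2.99e-15, and adjusted p = 0.00164 with an estimated correlation). HSFA7B (AT3G63350) rose by 14.33 ± 0.33, HSFB2A (AT5G62020) by 6.64 ± 0.18 and HSFB1 (AT4G36990) by 6.23 ± 0.23, whereas HSFA1A fell by 1.32 ± 0.18.

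Of 3 galactinol synthase genes, which make raffinose family precursors, 2 rose and 1 fell, also when adjusted over the list alone, led by GOLS1 (AT2G47180) at 10.16 ± 0.28 (list adjusted p = 0.00101, and adjusted p = 0.0216 with an estimated correlation). Splicing factor genes rose in 11 of 13 cases, 11 when adjusted over the list alone (median 0.59, adjusted p = 1.15e-07, and adjusted p = 0.0231 with an estimated correlation), led by SR45A (AT1G07350) at 6.00 ± 0.12, but with library size alone 4 rose and 6 fell. Of 15 genes of the unfolded protein response of the endoplasmic reticulum 9 rose and 4 fell, also when adjusted over the list alone, and 8 and 6 with library size alone. That list had an adjusted p = 6.84e-08, and adjusted p = 0.0715 with an estimated correlation. Its luminal HSP70 BIP1 (AT5G28540, near-identical to BIP2) rose by 3.47 ± 0.092 and the co-chaperone ERDJ3A (AT3G08970) by 7.78 ± 0.20. Of 20 genes of abscisic acid response 14 rose and 2 fell, also when adjusted over the list alone (adjusted p = 0.000745, and adjusted p = 0.274 with an estimated correlation), and 8 and 6 with library size alone. KIN1 (AT5G15960) rose by 4.13 ± 0.26 and CYP707A3 (AT5G45340), an abscisic acid 8'-hydroxylase, by 4.46 ± 0.14. Early general stress and touch genes rose in 10 of 14 cases, 10 when adjusted over the list alone (adjusted p = 0.00084, and adjusted p = 0.154 with an estimated correlation), and 6 rose and 3 fell with library size alone. ZAT12 (AT5G59820) rose by 6.02 ± 0.34 and TCH4 (AT5G57560) by 5.46 ± 0.27. Of 19 light harvesting and Rubisco genes 4 rose and 11 fell, 4 and 12 when adjusted over the list alone and 0 and 16 with library size alone (adjusted p = 0.00084, and adjusted p = 0.363 with an estimated correlation). LHCB1.1 (AT1G29920), which shares reads with its close copies, fell by 3.83 ± 0.19.

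Single markers of roots, stomata and seeds were called, but none of these 3 lists was called with an estimated correlation. Of 11 root markers 1 rose and 8 fell, also when adjusted over the list alone, and 0 and 9 with library size alone (adjusted p = 0.0316, and adjusted p = 0.34 with an estimated correlation). COBL9 (AT5G49270), a root hair gene, fell by 2.13 ± 0.22. Of 3 stomatal lineage markers 2 fell, 2 when adjusted over the list alone (adjusted p = 0.0357, and adjusted p = 0.0769 with an estimated correlation), TMM (AT1G80080) by 2.21 ± 0.12. Among 6 seed and embryo markers 4 were called higher, 4 when adjusted over the list alone, but the list did not pass its test (adjusted p = 0.645). Of 8 reference genes 7 were higher and 1 lower, also when adjusted over the list alone (adjusted p = 0.011, and adjusted p = 0.0568 with an estimated correlation), and with library size alone 2 were higher and 4 lower. Oxidative stress enzymes were called higher in 7 and lower in 4 of 12 cases, also when adjusted over the list alone, and in 4 and 5 with library size alone (adjusted p = 0.0271, and adjusted p = 0.0568 with an estimated correlation). CSD2 (AT2G28190), a plastid superoxide dismutase, fell by 1.77 ± 0.092. Lists for the cell cycle (2 higher, 2 lower of 12), chromatin regulators (10 and 9 of 27), the clock and thermomorphogenesis (4 and 5 of 15) and defence (0 and 2 of 7) did not pass the test (adjusted p = 0.855, 0.645, 0.646 and 0.542). Adjusted over the list alone these counts were 1 and 1, 10 and 9, 4 and 5, and 0 and 2, and with library size alone 0 and 6, 3 and 18, and 2 and 11 in the first 3. RPF3 (AT1G62930), a mitochondrial RNA processing factor, fell by 5.98 ± 0.34. XTH13 (AT5G57540), a cell wall enzyme, fell by 5.74 ± 0.49. In batch 1 alone 14301 genes were called.

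Heat in the libraries labelled eTK was compared with control to ask what part of the response is seen in that line. HSP101 rose by 1.11 ± 0.14, from 7.14 ± 0.477 CPM (SD, n = 6) to 14.0 ± 1.35 (n = 3, adjusted p = 2.17e-06). HSP21 was at 0.0172 CPM in control and 0.0430 CPM in heat and was not called (1.58 ± 1.13, adjusted p = 0.25). HSFA2 rose by 5.85 ± 0.35 to 9.35 ± 1.33 CPM (adjusted p = 2.64e-10) and DREB2A by 3.38 ± 0.22 to 34.5 ± 1.71 CPM (adjusted p = 5.97e-10). BIP2 (AT5G42020, chromosome 5, 16807342 to 16810693, near-identical to BIP1) rose by 4.39 ± 0.10 from 247 ± 20.3 CPM to 5142 CPM (5030 to 5220 in the 3 heat libraries) (adjusted p = 7.32e-16). In all, 12648 genes were called, 6125 higher and 6523 lower, and 1542 and 2327 of these by at least 2-fold. With library size alone, which put the median of all genes at −0.092, 4971 were higher and 7378 lower.

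All 15 unfolded protein response genes rose in the libraries labelled eTK, 15 when adjusted over the list alone (median 2.22, adjusted p = 7.93e-49, and adjusted p = 0.000811 with an estimated correlation), ERDJ3A by 3.76 ± 0.18. Early general stress and touch genes rose in 12 of 14 cases, 12 when adjusted over the list alone (median 2.35, adjusted p = 1.46e-09, and adjusted p = 0.0337 with an estimated correlation), with TCH4 at 3.85 ± 0.26 and the zinc finger repressor ZAT10 (AT1G27730) at 3.50 ± 0.26. Of 19 small heat shock protein genes 10 rose and none fell, also when adjusted over the list alone (median 1.02, adjusted p = 0.00762, and adjusted p = 0.0337 with an estimated correlation). HSP17.8-CI (AT1G07400) rose by 3.09 ± 0.18 and HSP17.6C-CI by 2.41 ± 0.40. HSP70, HSP90 and HSP100 genes were called higher in 9 and lower in 2 of 19 cases, also when adjusted over the list alone, and the list did not pass the test (adjusted p = 0.0673, and 0.0248 in batch 1 alone). HSP70-4 rose by 2.97 ± 0.33. Co-chaperones were called higher in 10 and lower in 1 of 11 cases, also when adjusted over the list alone (adjusted p = 0.00502, and adjusted p = 0.222 with an estimated correlation). The member that fell was BAG6 (AT2G46240), by 1.79 ± 0.12. Heat stress memory genes rose in 6 of 10 cases, 6 when adjusted over the list alone (adjusted p = 0.000514, and adjusted p = 0.017 with an estimated correlation), APX2 by 3.50 ± 0.37. Heat-responsive regulators were called higher in 10 and lower in 1 of 15 cases, also when adjusted over the list alone (adjusted p = 3.3e-06, and adjusted p = 0.157 with an estimated correlation). Heat shock factors were called higher in 12 and lower in 6 of 21 cases, also when adjusted over the list alone (adjusted p = 0.000717, and adjusted p = 0.222 with an estimated correlation), with HSFA6B (AT3G22830) up by 4.35 ± 0.19, and HSFA1A fell by 2.61 ± 0.18.

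**Figure D3:**
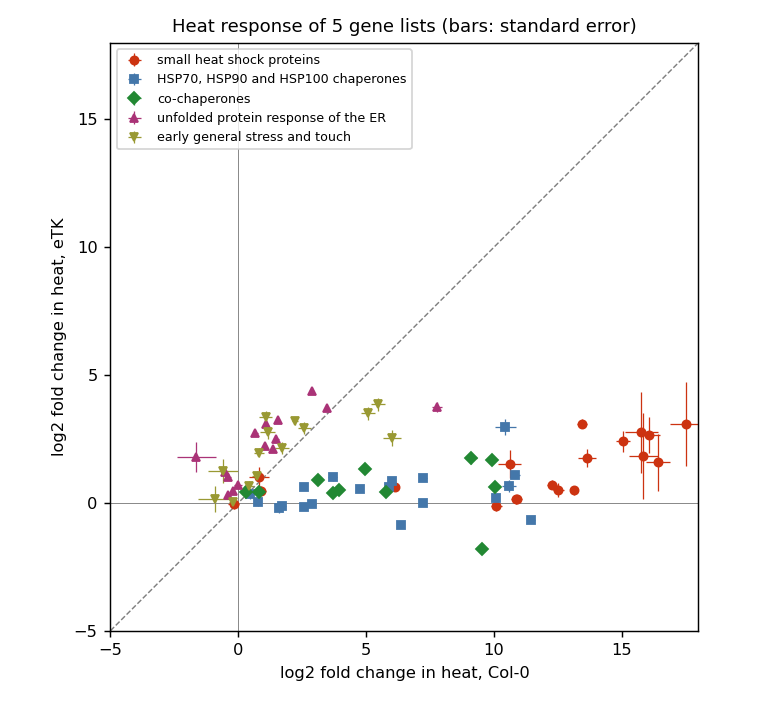
Log2 fold change in heat in Col-0 (x axis) and in the libraries labelled eTK (y axis) for the genes of 5 lists, with bars for the SE and a dashed line where both are equal. The small heat shock proteins had a median of 12.52 in Col-0 and 1.02 in libraries labelled eTK, and HSP21 lies at 16.42 and 1.58.

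Of 20 abscisic acid response genes 14 rose and 1 fell in the libraries labelled eTK, also when adjusted over the list alone (adjusted p = 1.09e-07, and adjusted p = 0.205 with an estimated correlation), with CYP707A3 up by 5.84 ± 0.14. Light harvesting and Rubisco genes were called higher in 3 and lower in 14 of 19 cases, 3 and 15 when adjusted over the list alone (adjusted p = 1.09e-07, and adjusted p = 0.222 with an estimated correlation). Splicing factors were called higher in 12 of 13 cases, 12 when adjusted over the list alone (adjusted p = 0.00144, and adjusted p = 0.225 with an estimated correlation). Reference genes were called higher in 6 and lower in 1 of 8 cases, also when adjusted over the list alone (adjusted p = 0.00483, and adjusted p = 0.0337 with an estimated correlation). Root markers were called higher in 1 and lower in 7 of 11 cases and stomatal markers in 1 and 2 of 3 (0 and 2 with library size alone), and neither list passed the test (adjusted p = 0.207 and 0.247). No other list was called: chromatin regulators were higher in 7 and lower in 12 of 27 cases (4 and 13 with library size alone, adjusted p = 0.614), and seed and embryo markers higher in 1 of 6 (adjusted p = 0.859), with a median of −0.72 while the test pointed up. The largest rises outside the lists were those of AT5G10340, an F-box protein gene, by 8.06 ± 0.58 and AT1G33760, an AP2/ERF-type factor gene, by 7.78 ± 0.42. GLL22 (AT1G54000), a lipase-like gene, fell by 4.82 ± 0.21 and AGO2 (AT1G31280), an Argonaute gene, by 4.22 ± 0.17. In batch 1 alone 12543 genes were called.

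The difference of the heat response between the lines was tested as an interaction, which asks which heat responses depend on genotype. HSP21 rose less in the libraries labelled eTK, with a log2 difference of −14.83 ± 1.75 (adjusted p = 3.46e-06), and so did HSP17.6C-CI (−12.64 ± 0.64), HSP70-5 (−12.15 ± 0.19), HSP90.1 (−9.93 ± 0.36) and HSP101 (−9.73 ± 0.23, adjusted p = 2.38e-16). HSFA7B differed by −13.42 ± 0.59, HSFA2 by −8.03 ± 0.49, MBF1C by −7.68 ± 0.22, DREB2A by −5.08 ± 0.31 and HSFB1 by −5.11 ± 0.29. The test called 5707 genes, 2848 higher and 2859 lower. Among the 7091 genes higher in heat in Col-0, 2271 (32.0%) rose less in the libraries labelled eTK, against 893 if the calls were independent. Both calls use the Col-0 libraries with opposite sign, so spread in these libraries alone can link them. The 893 is therefore no baseline for lines without a difference. In a simulation with the same heat effect in both lines, 0 of 6469 genes called higher in Col-0 rose less. Its counts were drawn from the model's own spread, which leaves almost no such calls by construction. It also gave both lines the same shift of composition in heat, unlike the real libraries. It therefore cannot show how many of the 2271 would arise where the model is wrong. Of the 2075 genes at least 2-fold higher, 1204 (58.02%) did so, and of the 404 at least 16-fold higher, 251 (62.1%). Those 404 genes had a median of 6.02 in Col-0 and 1.78 in the libraries labelled eTK, and 132 of them were at least 16-fold higher in both lines. Mitochondrial genes made up 65 of the 404 and 55 of the 132, and the 339 nuclear genes had a median of 6.02 in Col-0 and 1.04 in the libraries labelled eTK, with a smaller rise in 240 (70.8%). In both lines 4499 genes were called higher, against 1914 if independent, and 5110 were called lower, against 2115. With library size alone 93.3% of the calls were higher, since that scaling moved the median of all genes by 0.63, and the count of smaller rises was 830. In batch 1 alone, the only batch with heat, the difference called 4445 genes, and 3955 of these were among the 5707.

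Lists of chaperones, co-chaperones, regulators and memory genes lay lower in the difference. Of 19 small heat shock proteins 16 were lower and none higher, also when adjusted over the list alone (median −11.55, adjusted p = 4.16e-93, and adjusted p = 1.45e-09 with an estimated correlation). Of 19 HSP70, HSP90 and HSP100 genes 18 were lower (median −5.15, adjusted p = 8.37e-134, and adjusted p = 2.17e-07 with an estimated correlation), and of 11 co-chaperones 10 (median −3.63, adjusted p = 2.36e-92, and adjusted p = 9.12e-08 with an estimated correlation). ROF2 differed by −9.41 ± 0.23 and BAG6 by −11.32 ± 0.18. Of 15 heat-responsive regulators 12 were lower and 2 higher (adjusted p = 1.38e-45, and adjusted p = 8.42e-05 with an estimated correlation), and of 10 memory genes 9 were lower (adjusted p = 1.55e-37, and adjusted p = 5.24e-08 with an estimated correlation), APX2 by −9.44 ± 0.64. Counts adjusted over the list alone were the same for these lists. Of 21 heat shock factors 12 were lower and 4 higher, also when adjusted over the list alone, and 8 and 5 with library size alone (adjusted p = 9.4e-13, and adjusted p = 0.0147 with an estimated correlation). Both called galactinol synthases of 3 were lower, also when adjusted over the list alone (adjusted p = 2.73e-05, and adjusted p = 0.0294 with an estimated correlation), GOLS1 by −9.58 ± 0.37.

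Genes of the unfolded protein response went the other way. Of 15 genes 13 rose more in the libraries labelled eTK and 1, ERDJ3A, rose less (−4.02 ± 0.25), also when adjusted over the list alone. The list had a median of 1.19 (adjusted p = 1.94e-12, and adjusted p = 0.0233 with an estimated correlation). The calreticulin gene CRT2 differed by 2.08 ± 0.13 and HSP90.7, the HSP90 of the endoplasmic reticulum, by 2.00 ± 0.12, both named after their values were seen. Splicing factors were lower in 3 of 13 cases, 3 when adjusted over the list alone (adjusted p = 7.7e-05, and adjusted p = 0.168 with an estimated correlation), with SR45A at −5.28 ± 0.16, while with library size alone 10 were higher and 3 lower. For chromatin regulators, 3 of 27 were higher and 6 lower, also when adjusted over the list alone, the list was not called (adjusted p = 0.282), and with library size alone 19 were higher and 3 lower. The histone chaperone ASF1B (AT5G38110) differed by −1.77 ± 0.16 and the remodeller CHR11 (AT3G06400) by −1.39 ± 0.12. Seed and embryo markers were lower in 4 of 6 cases, 4 when adjusted over the list alone, with a list adjusted p = 0.652 and 0.0498 with library size alone. Abscisic acid response genes were called higher in 5 and lower in 5 of 20 cases and early stress genes in 4 and 3 of 14. Adjusted over the list alone these were 6 and 5, and 5 and 3, and with library size alone 13 and 4, and 10 and 3 (list adjusted p = 0.652 and 0.381). The remaining lists were not called in the difference. Among them 0 of 12 cell cycle genes and 2 of 19 light harvesting and Rubisco genes, both lower, passed the test, with the same counts adjusted over the list alone, and 3 and 12 higher with library size alone.

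The control libraries of both lines were compared to ask whether they differ without heat. Chaperone transcripts were lower in the libraries labelled eTK, with log2 differences of −1.06 ± 0.11 for HSP101 (adjusted p = 5.78e-07), −2.76 ± 0.18 for HSP90.1 (adjusted p = 1.66e-09), −2.60 ± 0.28 for HSP70-4 (adjusted p = 1.46e-06) and −2.76 ± 0.27 for HSP17.6C-CI (adjusted p = 2.82e-07). HSFA2 was lower, at −1.98 ± 0.31 (adjusted p = 8.58e-05), and so was MBF1C, at −0.79 ± 0.11 (adjusted p = 3.05e-05), while HSP70-5 was higher by 1.21 ± 0.086 (adjusted p = 4.64e-09). DAR4 (AT5G17890, chromosome 5, 5916862 to 5923494), a resistance protein of the TIR-NBS-LRR type, was lower, at −12.56 ± 0.15 (adjusted p = 2.26e-20). The test called 6171 genes, 3049 higher and 3122 lower, and 671 and 994 of these by at least 2-fold. Fits of the 6 controls of a batch called 8179 genes in batch 1, 3997 higher and 4182 lower, and 3571 in batch 2, 1223 higher and 2348 lower, while a fit of all batch 1 libraries, heat included, called 5108 between the controls. Several differences were larger in batch 2, with −0.77 and −1.36 for HSP101 in batches 1 and 2, −2.21 and −3.30 for HSP90.1 and −1.71 and −3.47 for HSP70-4 (genotype by batch, adjusted p = 0.0241, 0.0172 and 0.0108). MBF1C was at −0.55 and −1.02 (adjusted p = 0.125). Of 2311 genes called in both batches 2232 (96.6%) had the same sign and 79 the opposite one. Across 21868 genes, which are not independent replicates, the differences of the batches had a Pearson r of 0.815 and a Spearman rho of 0.441.

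Of 19 small heat shock proteins 12 were lower and none higher in control, 13 when adjusted over the list alone (median −0.90, adjusted p = 4.71e-06, and adjusted p = 0.00307 with an estimated correlation). Of the 15 members tested in the fits of each batch, 10 were lower in batch 1 and 8 in batch 2. HSP23.5-MT (AT5G51440), a mitochondrial member, was lower, at −4.09 ± 0.34, with −2.83 in batch 1 and −5.59 in batch 2 (genotype by batch, adjusted p = 0.00587). Of 19 HSP70, HSP90 and HSP100 genes 13 were lower and 1 higher, 14 and 1 when adjusted over the list alone (adjusted p = 1.99e-08, and adjusted p = 0.149 with an estimated correlation), with 15 lower in batch 1 and 11 in batch 2. Co-chaperones were lower in 8 of 11 cases, 8 when adjusted over the list alone and 8 in each batch (adjusted p = 4.71e-06, and adjusted p = 0.135 with an estimated correlation). Unfolded protein response genes were lower in 6 and higher in 1 of 15 cases, 7 and 1 when adjusted over the list alone (adjusted p = 0.0109, and adjusted p = 0.668 with an estimated correlation). Abscisic acid response genes were higher in 14 of 20 cases and lower in none, 16 and 1 when adjusted over the list alone (median 0.63, adjusted p = 4.71e-06, and adjusted p = 0.405 with an estimated correlation), with 17 higher in batch 1 and 6 in batch 2. RD29B (AT5G52300), a desiccation-responsive gene, was higher by 3.60 ± 0.30 (4.26 in batch 1 and 2.85 in batch 2) and COR15A (AT2G42540), a cold-regulated gene, by 2.89 ± 0.45 (3.62 and 1.63), without a call for genotype by batch (adjusted p = 0.0941 and 0.104). Seed and embryo markers were higher in the same libraries in 5 of 6 cases, 5 when adjusted over the list alone (median 3.17, adjusted p = 0.0454, and adjusted p = 0.712 with an estimated correlation). Of the 4 markers tested in the fits of each batch, 4 were higher in batch 1 and 3 in batch 2. The cruciferin gene CRA1 (AT5G44120) was higher by 4.63 ± 0.97.

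Light harvesting and Rubisco genes were higher in 15 and lower in 1 of 19 cases, also when adjusted over the list alone (median 0.54, adjusted p = 6.07e-08, and adjusted p = 0.405 with an estimated correlation), 14 higher in batch 1 and 13 in batch 2. Defence genes were lower in 3 of 7 cases, 4 when adjusted over the list alone (adjusted p = 0.0323, and adjusted p = 0.516 with an estimated correlation), with an adjusted p = 0.285 in the fit of all batch 1 libraries. FRK1 (AT2G19190), a receptor kinase gene, was lower, at −4.94 ± 0.70, as was PR5 (AT1G75040), at −1.58 ± 0.14. No other list was called. Clock and thermomorphogenesis genes were higher in 6 of 15 cases, 6 when adjusted over the list alone (adjusted p = 0.226, and 0.00417 in the fit of all batch 1 libraries), and in fits of the controls of a batch 8 were higher in batch 1 and 0 in batch 2. Chromatin regulators were higher in 2 and lower in 2 of 27 cases, 2 and 1 when adjusted over the list alone, among them the deacetylase gene HDA9 (AT3G44680) at −0.62 ± 0.074. Several transcripts were present in a single line. Against a floor of 3 counts, AT5G28919 was 5756-fold lower in the libraries labelled eTK and AT5G36930, a TIR-NBS-LRR gene, 3553-fold. AT4G01595 was lower by 2395-fold and AT3G18535 by 2200-fold on the same floor, each of the 4 from 0 counts over the group. AT4G19240 was higher by 11.46 ± 0.24, AT3G60950 by 11.19 ± 0.31 and AT5G27010 by 10.67 ± 0.26. These SE may be far too small, since the transcripts were near absent in Col-0 control. AT3G61030 had 2 counts over the Col-0 control libraries, a log2 ratio of 11.75 with a 95% counting interval from 9.90 to 14.8. That interval may be too narrow, since mates appear to have been counted singly.

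The heat libraries of both lines were compared to show the levels reached in heat. HSP21 was lower in the libraries labelled eTK, with a log2 difference of −15.91 ± 0.46 (adjusted p = 3.26e-15), and so were HSP17.6C-CI (−15.40 ± 0.28), HSP90.1 (−12.68 ± 0.37), HSP101 (−10.79 ± 0.22), HSFA2 (−10.01 ± 0.40) and APX2 (−9.54 ± 0.26). HSP101 reached 24690 ± 2910 CPM in Col-0 and 14.0 ± 1.35 in libraries labelled eTK (SD, n = 3 each), and BIP2 1531 ± 84.3 CPM in Col-0 and 5142 CPM (5030 to 5220) in the libraries labelled eTK. The test called 10520 genes, 5285 higher and 5235 lower, and with library size alone 90.15% were higher. That scaling moved the median of all genes by 0.64, and in batch 1 alone 10979 genes were called. Small heat shock proteins were lower in 17 of 19 cases (adjusted p = 4.78e-106, and adjusted p = 1.92e-10 with an estimated correlation) and HSP70, HSP90 and HSP100 genes in 18 of 19, with the same counts when adjusted over the list alone (adjusted p = 1.36e-103, and adjusted p = 8.13e-07 with an estimated correlation). Unfolded protein response genes were higher in 12 and lower in 2 of 15 cases, also when adjusted over the list alone (adjusted p = 6.86e-07, and adjusted p = 0.106 with an estimated correlation). Abscisic acid response genes were higher in 12 and lower in 3 of 20 cases, also when adjusted over the list alone, and 17 and 1 with library size alone, where the list was not called (adjusted p = 0.0062, adjusted p = 0.0634 with library size alone, and adjusted p = 0.528 with an estimated correlation). Light harvesting and Rubisco genes were higher in 7 and lower in 2 of 19 cases, also when adjusted over the list alone, and 15 and 0 with library size alone (list adjusted p = 0.0561, and 0.00772 with library size alone). RD29B was higher by 4.12 ± 0.42 and COR15A by 4.68 ± 0.64. Against a floor of 3 counts, AT1G19550, a glutathione transferase family gene, was 1827-fold higher and AT5G27010 1241-fold higher in the libraries labelled eTK, from 0 counts over the Col-0 group.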

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

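Tests chosen only after their result was seen were those of the scaling and of shared BIP reads for the unfolded protein response, both tests of transcripts present in a single line, the count of called genes with an upstream element, and the breakdown of groupings by mixed heat libraries. What was concluded from the median ratio between batches and from the permutation test of upstream elements was also settled after these values were seen.

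Among 217 values per group that were examined for a library set apart from the others of its group, 9 had one, where chance gives about 1 in 20. In Col-0 control, UBQ10 was at 1445 CPM in replicate 4 and at 1290 to 1337 in the others, and BIP1 at 229 CPM in replicate 3 and 266 to 287 in the others. XTH13 was at 11.8 CPM in replicate 4 (others 3.91 to 5.52) and HSFA6B at 2.81 CPM in replicate 6 (others 1.78 to 2.14). In control libraries labelled eTK, 3 of the 9 were in replicate 6: HSP70-4 at 5.48 CPM (others 2.62 to 3.64), HSFB2A at 9.46 CPM (others 5.19 to 5.81) and PYK10 at 3851 CPM (others 2003 to 2617). UBQ10 was at 1321 CPM in replicate 1 (others 1093 to 1176), and plastid and mitochondrial genes took 0.113% of the counts in replicate 5 (others 0.0391% to 0.0642%).

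The test of the difference between the heat responses of the lines put a further 55 values here, each the heat response of the libraries labelled eTK minus that of Col-0 on the log2 scale. Among small heat shock proteins, HSP21 was at −14.83, HSP23.6-MT at −14.44, HSP22.0-ER at −14.02, HSP17.6-CII at −13.41 and HSP17.6C-CI at −12.64. The call of HSP22.0-ER was lost without eTK control replicate 6 (−11.50, adjusted p = 0.998, and 1.74e-16 to 0.998 over all alternatives) and that of HSP23.6-MT without eTK control replicate 3 (−11.50, adjusted p = 0.999, and 1.2e-16 to 0.999 over all alternatives). Larger chaperones and co-chaperones were HSP70-5 at −12.15, BAG6 at −11.32, HSP90.1 at −9.93, HSP70T-2 at −9.90, HSP101 at −9.73, ROF2 at −9.41 and HSP70-4 at −7.47. Heat shock factors and regulators were HSFA7B at −13.42, HSFA2 at −8.03, HSFA7A at −7.70, MBF1C at −7.68, HSFB2A at −5.32, HSFB1 at −5.11, DREB2A at −5.08, HSFA1A at −1.30, HSFA1E at −0.95 and HSFA1D at −0.51. HSFA1B was at −0.66 (adjusted p = 0.0456) and kept its call in 4 of 18 settings with a library left out (without Col-0 control replicate 1 or eTK control replicate 3, eTK control replicate 5 or eTK heat replicate 2), with adjusted p from 0.00276 to 0.149 (to 0.912 with library size alone, the highest of all alternatives). The memory gene APX2 was at −9.44, the galactinol synthases GOLS1 at −9.58 and GOLS2 at −6.70, and the splicing factors SR45A at −5.28 and SR30 at −2.30. KIN1 was at −3.18, COR47 at −1.93, CCA1 at −2.37, PRR7 at −3.21, ZAT12 at −3.47, ASF1B at −1.77, CHR11 at −1.39, RCA at −0.715 and UBQ10 at −0.46. LHCB1.3 was at −0.52, without its call when eTK heat replicate 1 (−0.50, adjusted p = 0.054) or replicate 2 (−0.49, adjusted p = 0.0694) was left out, with adjusted p from 0.00285 to 0.621 over all alternatives. With library size alone HSFA1E (−0.32, adjusted p = 0.188, and 0.000297 to 0.188 over all alternatives) and RCA (−0.085, adjusted p = 0.603, and 7.38e-06 to 0.603) lost their calls, and HSFA1D (0.12), LHCB1.3 (0.11) and UBQ10 (0.18) changed sign. Without a batch term RCA (−0.72, adjusted p = 0.278), PRR7 (−3.43, adjusted p = 0.232, and 1.42e-48 to 0.232) and LHCB1.3 (−0.48, adjusted p = 0.621) lost theirs.

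The seed storage protein gene CRC was at −6.87, with 0.106 to 59.8 CPM in the Col-0 heat libraries, and without its call when Col-0 heat replicate 2 was left out (−5.07, adjusted p = 0.0518, and 0.0021 to 0.21 over all alternatives). SESA1, another such gene, was at −6.02, with 0 to 5.27 CPM in the Col-0 heat libraries, and kept its call in 9 of 18 settings (without Col-0 control replicates 4, 5 or 6, Col-0 heat replicate 3 or eTK control replicates 2, 3, 4, 5 or 6), with adjusted p from 0.00723 to 0.0797 (to 0.257 with limma-voom, the highest of all alternatives). The list of seed and embryo markers was not called in the difference (adjusted p = 0.652). Among genes higher in the difference, the peroxidase gene AT1G14550 was at 8.64, the F-box gene AT5G10340 at 5.19, FAF4 at 5.02, ERF6 at 2.27, FAMA at 2.06, MYB36 at 1.74, AOX1A at 1.00, TMM at 0.75 and SCR at 0.74. The fitted values of AT1G19550 (6.47) and AT5G28919 (6.15) involve a group with 0 counts and are no bounds. ICS1 was at 1.01 and lost its call without Col-0 heat replicate 2 (0.80, adjusted p = 0.0936), eTK heat replicate 1 (1.01, adjusted p = 0.0521) or eTK heat replicate 2 (0.96, adjusted p = 0.0687), with 0.000331 to 0.107 over all alternatives. NHL10 was at 1.52 and lost its call without Col-0 heat replicate 1 (1.37, adjusted p = 0.0683) or eTK heat replicate 1 (1.05, adjusted p = 0.109), with 0.000812 to 0.198 over all alternatives. ERDJ3A was at −4.02, and BIP3 at 3.42, without its call in batch 1 alone (2.11, adjusted p = 0.0851, and 0.000526 to 0.0851 over all alternatives).

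The first pattern weighed is the larger rise of unfolded protein response genes in heat in the libraries labelled eTK. Scaling of the Col-0 heat libraries, in which heat shock transcripts take a large share, is argued against, since a scaling factor moves all genes of a library alike and the median difference of the list was 1.19 relative to all genes (bootstrap interval 0.706 to 1.72) and 1.29 relative to the reference genes. Reads shared between BIP1 and BIP2 are argued against as the whole cause by a median of 1.09 in the 12 members without BIP genes (interval 0.701 to 1.71). Both intervals resampled genes as if independent, although the estimated correlation of the list was 0.356. They leave out the spread between libraries and are too narrow. A wider stress response of the endoplasmic reticulum stays open: the 105 other genes with its response element upstream had a mean difference no higher than genes without it (one-sided permutation p = 0.54), while 21.9% of them were called higher, against 12.5% (Fisher's exact test, p = 0.00722). A difference between the genotypes that the labels name may also be behind it and was not tested.

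The second pattern is the set of 178 genes whose control levels differed by at least 5 on the log2 scale between the lines, 67 higher and 111 lower in the libraries labelled eTK. Segments of another accession within 2 Mb of the 3 targeted genes are argued against as the whole cause. Within that distance lay 13.5% of the 178 genes and 10.8% of all tested genes (ratio 1.25), with 10 near HSFA1A, 14 near HSFA1B and 0 near HSFA1D. A window of 2 Mb cannot judge longer segments around the targeted genes. The set made up 1.18% and 1.26% of tested genes on chromosomes 4 and 5, which carry HSFA1A and HSFA1B. On chromosome 1, which carries HSFA1D, it made up 0.505%, and on chromosomes 2 and 3 0.377% and 0.629%. A difference between batches in growth or preparation is argued against for the 135 genes that differed this much in batch 1 and were measured in batch 2. Of these, 134 (99.3%) had the same sign and at least 2.5 in batch 2. Longer segments around the targeted genes, or segments elsewhere, could still account for the set. Its genes were clustered in windows of 1 Mb (permutation p = 1e-04, the smallest that 10000 permutations can give). The genotype itself, including other changes in the line labelled eTK, stays open and was not tested.

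The third pattern is that 8179 genes were called between the lines in a fit of the batch 1 controls and 3571 in one of the batch 2 controls, a gap that depends on the fit, since all batch 1 libraries together, heat included, gave 5108. Depth is argued against, because thinning batch 1 to the depth of batch 2 left 8026 calls. A larger spread between the replicates of batch 2 remains a candidate explanation, with a common dispersion 2.3 times that of batch 1 (0.0239 against 0.0104). Larger genotype differences in batch 1 stay open: the median ratio of batch 1 to batch 2 differences among genes called in batch 2 was 0.623, but the bound of 0.8 set for it was wrong, since choosing genes in a batch lowers the ratio, and the reverse ratio, 0.457, was lower still. The test of genotype by batch called 1332 genes, and a change in growth between batches was not tested.

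Other groupings of the same libraries were run for each comparison. For heat in Col-0, 1 of 84 groupings gave 14448 calls, the real one, and the highest other gave 8940, with the 3 batch 1 controls in place of the heat libraries. For heat in the line labelled eTK the same held for 12648 calls (1 of 84), with 7707 as the highest other, again from the batch 1 controls. Within batch 1 these groupings still set control against heat libraries, so the heat response itself can give such calls, and the real groupings called 14301 and 12543 genes in batch 1 alone. Heat was in batch 1 only, and groupings among the 84 also gave the heat label to batch 2 controls, although the control batches differed in 8250 genes. The share among the 84 therefore does not measure chance within batch 1, so neither count excludes chance. Between the lines in control, 1 of 100 groupings gave 6171 calls and the highest other 468, which argues against a random division of these libraries. The labels do not say that replicates came from separate cultures, so chance differences between cultures are not excluded. For the difference of the heat response, 7 of 100 groupings gave at least 5707 calls and the highest other gave 9623, so chance cannot be excluded by this count. Of 12 other groupings that left the heat libraries of each line unmixed, 6 gave as many, and 0 of the 87 that mixed them did (highest 1169). These 6 kept the heat libraries of the lines apart, so the difference between the lines in heat can give them. Within batch 1 the difference called 4445 genes. For the genes with a smaller rise, 2 of 100 groupings gave at least 2271, the highest other 3296. Of the 12 others that left the heat libraries unmixed, 1 gave as many, and the highest with mixed heat libraries was 420. Genes with a smaller rise are part of the calls of the difference, so chance is not excluded for them either. Between the lines in heat the 10 possible groupings are too few for a share under 0.05, with 10520 calls for the real one and 1 for the highest other.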

How the results depend on the processing

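The alternative with halved counts was added after the data were seen. Leaving out each of the 18 libraries in turn gave 13488 to 14603 genes for heat in Col-0, 11032 to 13135 for heat in the line labelled eTK, 4631 to 5832 for their difference, 5401 to 6703 between the lines in control, 9027 to 10858 in heat, and 1789 to 2349 genes with a smaller rise. With library size alone the difference called 15347 genes, the lines in heat 16939 and the smaller rise 830. That scaling leaves out composition, and the median of all genes was 0.63 in the difference, 0.64 between the lines in heat and −0.75 for heat in Col-0. A fold threshold of 2 left 5582, 3869, 2435, 1665 and 4053 genes in the 5 comparisons and 896 with a smaller rise, by its own construction. Counts under the other alternatives lay within 1.5 times the values reported: DESeq2 gave 14974, 13125, 6512, 6975, 11056 and 2581, limma-voom 13979, 12747, 5128, 6842, 9541 and 2169, and halved counts 14292, 12663, 5563, 6278, 10236 and 2173. Without a batch term they were 13230, 10787, 3944, 4300, 8303 and 1634. A fit of only the groups compared was not run for the difference and the smaller rise, which need all 4 groups.

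With the replicate number as a block in place of the batch, 14172, 12314, 5188, 5733, 10020 and 2001 genes were called. The numbers did not pair the samples: same-numbered libraries had a mean correlation of 0.0127 between their deviations, with 3 of 21 above 0.1, and differently numbered ones −0.00606, with 5 of 42.

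Of 292 named gene results 282 were called, and 230 kept their side of the threshold and their sign in all alternatives run. Leaving out a library ended the call of 22 in at least 1 of 18 settings, and 48 changed their call in an alternative that kept all libraries, library size aside. With library size alone 6 changed sign: PCNA1 for heat in Col-0 (−0.017) and between the lines in heat (0.15), LHCB1.3 (0.11), HSFA1D (0.12) and UBQ10 (0.18) in the difference, and EF1A (0.23) between the lines in heat. None of these was called there, and their shifts follow from this scaling, which moves all genes of a comparison alike, by the change of the median given above. Of 105 list results 26 lost their call with an estimated correlation, and fry called 19 more. Library size alone ended 6 and added 2, batch 1 alone ended 1 and added 2, and the block added 1. In simulated data the test of the difference called 10.7% of 1.5-fold changes. No other depth was simulated, and halved counts moved its calls only from 5707 to 5563, so this share is not shown to come from depth.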

Other observations

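Tests of 25 gene families, chosen after the data were seen, described groups outside the lists above. Genes of the mitochondrial genome rose in heat in 73 of 74 cases in Col-0 (median 5.56) and in 73 of 74 in the libraries labelled eTK (median 4.75), and in 73 of 74 with library size alone in both. This was the single family that kept its call with an estimated correlation (adjusted p = 0.0177 and adjusted p = 0.00275). ATMG00690 rose by 7.32 ± 0.29 and ATMG00630 by 7.65 ± 0.45 in the libraries labelled eTK. Plastid genes were higher in 40 of 74 cases in Col-0 (8 higher and 7 lower with library size alone), and higher in 4 and lower in 11 in the libraries labelled eTK. In the difference 35 of them were lower and none higher, and 13 with library size alone (adjusted p = 0.000311, and adjusted p = 0.803 with an estimated correlation). They were already higher in 27 and lower in 2 cases in the controls labelled eTK (30 and 2 with library size alone, median 0.58, adjusted p = 0.00321, and adjusted p = 0.933 with an estimated correlation), which enters that difference, and replicate 5 of these controls stood apart in its share of organelle counts (0.113%). The labels name total RNA as the extracted molecule and do not say how libraries were selected from it. Plastid and mitochondrial genes together took only 0.0332% to 0.132% of the counts of a library. Changes in organelle genes are therefore changes in the part that was captured, and were not shown to be changes in transcript abundance.

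Pentatricopeptide repeat genes, whose products act on organelle transcripts, fell in 196 of 270 cases in heat in Col-0 (median −1.09) and in 190 in the libraries labelled eTK (median −0.83), and with library size alone in 243 and 208 (adjusted p = 6.31e-10 and 4.31e-13, and adjusted p = 0.667 and 0.398 with an estimated correlation). WRKY factor genes were higher in the difference in 20 and lower in 1 of 61 cases, and 51 and 0 with library size alone (adjusted p = 0.000311, and adjusted p = 0.719 with an estimated correlation). In the controls labelled eTK they were lower in 25 and higher in 1 (adjusted p = 3.96e-05, and adjusted p = 0.933 with an estimated correlation), and between the lines in heat they were higher in 19 and lower in 12 (39 and 3 with library size alone) without a call (adjusted p = 0.251). WRKY17 fell by 1.60 ± 0.13 in Col-0 and rose by 1.02 ± 0.12 in the libraries labelled eTK, a difference of 2.62 ± 0.17 (adjusted p = 4.75e-10). SAUR genes, which auxin induces, were higher in the difference in 28 and lower in 4 of 71 cases, and 43 and 2 with library size alone (adjusted p = 0.000624, and adjusted p = 0.719 with an estimated correlation). In control, TIR-NBS-LRR resistance genes were lower in the libraries labelled eTK in 37 and higher in 7 of 87 cases under each scaling run (adjusted p = 4e-11, and adjusted p = 0.826 with an estimated correlation), and in the difference they were higher in 32 and lower in 9 (64 and 7 with library size alone, adjusted p = 0.00206, and adjusted p = 0.727 with an estimated correlation).

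A hypothesis set down before its test was that genes with a smaller rise in the libraries labelled eTK carry heat shock elements. Among genes at least 2-fold higher in heat in Col-0, 41 of 1169 with a smaller rise had a 3-unit element within 500 bp upstream (3.51%), against 7 of 802 others (0.873%) and 0.71% of all other tested genes. The odds ratio was 4.13 (95% interval 1.82 to 10.95, Fisher's exact test, two-sided p = 0.00014), and 3.92 with genes stratified by the size of their rise (p = 0.000227). The elements may mark genes that HSFA1 factors act on directly, but most genes with a smaller rise had none.

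Another hypothesis was that the heat response is less active in the line labelled eTK without heat, read from batch 2 controls. These controls also entered the model that chose the genes, so the choice and the test are not independent. Genes at least 2-fold higher in heat in Col-0 had a median control difference of −0.0279 in batch 2, below the 0.002875 that 2.5% of 10000 random sets matched on expression fell under (median of the sets 0.0186). Of these 1836 genes 294 were called lower in batch 2 and 113 higher, where all tested genes gave 2348 lower and 1223 higher. In the 243 genes at least 16-fold higher the median was −0.31, with 80 called lower and 10 higher. The shift over the whole set is very small and could have other origins, which were not tested.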
